A study of Homo sapiens with 8 samples.

How the data were processed

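Total RNA of 8 human breast cell cultures was measured on 8 Illumina HumanRef-8 v3 bead arrays: SUM1315, MDA-MB231 and SUM159 untransfected, SUM159 with IRX5 or LacZ, and HMLE with LacZ, Gcnt2 or Foxq1. Groups were taken from the labels, 1 array each. The deposited value table holds, per array, probe intensity on a linear scale from 73.3 to 56056.2; the authors' values, sorted within each array, differ between arrays by a coefficient of variation of at most 1.19%, so they are quantile-normalized. GenomeStudio, lumi 1.14 and R 2.11.1 are named in the submitters' processing notes, which give no role to any of them, and the authors' background correction is not given in the sources used here. A second table of unnormalized values was not used: its 8 signal columns and 8 detection columns, 16 in all, carry names that no label ties to a sample. Of the 24526 probes, 21834 have 1 gene symbol in the platform annotation, none has several and 2692 are unnamed. Symbols of 21813 probes were updated through their Entrez number with the RefSeq annotation, used only for names, and 21 kept the name of the array annotation. They stand for 16922 genes, 3195 of them with more than 1 probe.

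With no detection p-value mapped to a sample, the normalization planned first (neqc) could not be run, and the fallback written beside it was used: the deposited intensities were background-corrected with normexp (limma 3.58.1 in R 4.3.3, offset 50) and put on a log2 scale, with no second quantile step because the values already were normalized. A gene is its named probe with the highest mean over the 8 arrays. In place of detection p-values, and defined after the values were seen, the detection limit came from the spread of intensities below their mode of 109.9, mirrored above it, at a tail of 0.01, which gave 143; a tail of 0.05 gave 132. A gene was compared where at least 1 array of the pair lay above the limit. Where the dimmer array did not, the fold was computed with that array at the limit and written as "at least", and no fold was given where neither did. All folds are of background-corrected values and mostly exceed ratios of the deposited intensities. An "at least" fold is therefore a bound on the corrected scale only and can exceed the ratio of the intensities. Medians of lists use the measured values, and the text adds the median with dim values at the limit where that falls inside the random range. The median intensity of an array was 1.45 times the mode, so about 4 in 10 genes lie too near background for a fold. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

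No test was made between single arrays. Differences of at least 2-fold were counted, beside the count for LacZ against untransfected SUM159, and a difference was said to exceed the reference spread where it passed percentile 99 of that pair for genes of like intensity (10 bins). For IRX5, genes beyond both SUM159 controls were counted. For the lines, a gene counted as highest or lowest where it differed 2-fold from each of the other lines. The differences of both HMLE arrays from their shared LacZ control were correlated across genes and set beside 100 simulations with no effect. For each of 26 gene lists with at least 5 detected members, the median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and called outside the range below percentile 2.5 or above percentile 97.5. The lists were epithelial junction and differentiation, mesenchymal and EMT, basal and myoepithelial, luminal, stem cell associated, cell cycle, interferon response, inflammatory cytokines and NF-kB, TGF-beta pathway and targets, WNT pathway, EGFR and MAPK targets, integrins, matrix proteases and inhibitors, glycosyltransferases, Iroquois and HOX homeobox, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and amino acid stress, p53 targets, antigen presentation, cancer-testis antigens, ribosomal proteins, leukocyte, endothelial, adipocyte, and melanocytic or neural. Gene members, comparisons, the rule for named genes and most alternatives were fixed before the data were examined.

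Named genes followed this rule: FOXQ1, GCNT2 and IRX5 in all arrays; for IRX5 the 10 genes highest and the 10 lowest against the control nearer to it; for Foxq1 and Gcnt2 the 10 highest and the 10 lowest against LacZ; for each line the 7 highest and the 5 lowest against the nearer line; up to 3 members per direction of each list that differed 2-fold; and CDH1, CDH2, VIM, FN1, EPCAM and CD44. Unnamed and open reading frame names were left out, and 1 gene named by the rule is not reported here. A gene whose detected probes differ in sign is called inconsistent.

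The calculations were tested on simulated data made for the comparison of Foxq1 with LacZ with the reference spread (9759 genes, 40 changed genes per fold). At 1.5-fold 17.5% of changed genes were called, at 2-fold 50%, at 3-fold 87.5%, at 4-fold 97.5% and at 8-fold 100%, with 4.58% of 9559 unchanged genes called. All 130 genes placed beyond both controls or other lines were found. Of 100 unchanged lists 6% lay outside the random range (9559 genes), and 100% of lists shifted by 0.5 on the log2 scale lay above it. These lists were random genes with noise drawn gene by gene, so the 6% does not hold for genes that vary together. In the real reference pair several of the fixed lists lay outside the range, as given in the results. All 40 probes lowered 8-fold in genes with several probes were found (584 genes). For IRX5 against both SUM159 controls (11165 genes), limma called 98.5% of 200 genes changed 8-fold and 47 unchanged ones; with no gene changed it called at most 11 in 20 simulations.

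Alternatives tried were the deposited values on a log2 scale with no background correction, an offset of 16, cyclic loess or median scaling between arrays, the other detection limits, detection in every array compared, the mean of all detected probes, a 1.5-fold threshold, other control arrays, limma for IRX5, list means, and correlation over genes detected in all 3 HMLE arrays. Loess and median scaling were run on values already quantile-normalized, so neither replaced that normalization. Chosen after seeing the data were subtraction of the mode, a detection limit of 200, dim values raised to the limit, the probe nearest to 0, genes with 2 bright probes, and HMLE noise in the simulations of the HMLE arrays and of IRX5.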

Results

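Messenger RNA levels were measured on 8 Illumina bead arrays, 1 per group, from human breast cell lines. SUM1315, MDA-MB231 and SUM159, which the design text calls basal-like breast cancer cells, were profiled without a transgene. SUM159 was also profiled after stable transfection with IRX5, an Iroquois homeobox transcription factor, and with LacZ, the bacterial beta-galactosidase gene that served as the control. HMLE cells are human mammary epithelial cells immortalized with telomerase and SV40 large T antigen, and were profiled with LacZ, with Gcnt2, a glycosyltransferase that builds branched I antigen chains, and with Foxq1, a forkhead transcription factor. Each array held 24526 probes, of which 21834 were assigned to 16922 genes. Between 10250 genes (untransfected SUM159) and 10593 genes (the array labelled Foxq1) lay above the detection limit, and the median intensity was close to 160 in every array after normalization (159.7 to 159.9). With 1 array per group no difference has a replicate check, and no p-value is given for a single pair of arrays. The untransfected and LacZ arrays of SUM159, which differ by the vector, give the reference spread: 416 of 10867 genes (3.83%) lay at least 2-fold apart there. A fold written as "at least" sets the dimmer array at the detection limit. Folds are of background-corrected values, so a fold, also one written as "at least", can exceed the ratio of the intensities.

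The 3 introduced genes were examined first. The probe for GCNT2 transcript NM_145649 read 106 in HMLE LacZ and 9104 in HMLE Gcnt2, at least 81.0-fold higher, and it lay between 89.1 and 157 in the other 7 arrays. The other 3 GCNT2 probes read 106, 129 and 122 in HMLE Gcnt2 against 107, 123 and 113 in HMLE LacZ. The single FOXQ1 probe went against its label: it read 299 in the array labelled Foxq1, 1641 in HMLE LacZ and 1378 in HMLE Gcnt2, 6.0-fold lower than in LacZ. Among the other lines FOXQ1 read 1111 in untransfected SUM159, 2518 in SUM159 LacZ, 1568 in the array labelled IRX5, 196 in MDA-MB231 and 126 in SUM1315, below the limit of 143. The single IRX5 probe was not higher in the array labelled IRX5: it read 151 there, 165 in SUM159 LacZ and 163 in untransfected SUM159, while SUM1315 read 1216 and the 3 HMLE arrays between 211 and 353. The species and extent of the constructs are not given in the sources used here. A probe outside a construct checks nothing, so neither probe settles whether the transgene was present, and every direction given for the arrays labelled Foxq1 and IRX5 rests on the label alone.

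**Figure D1:**
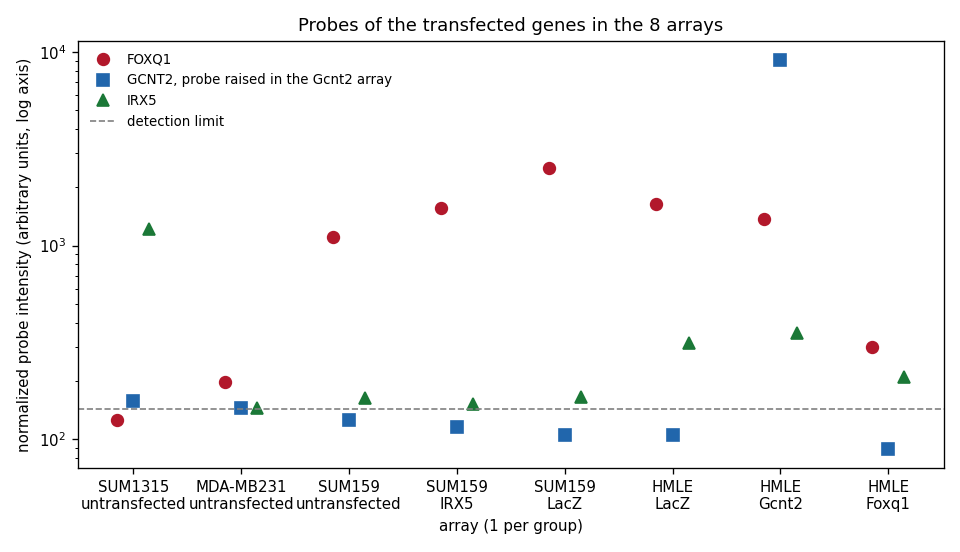
Normalized probe intensity (arbitrary units, log axis) of FOXQ1, of the GCNT2 probe that was raised and of IRX5 in each of the 8 arrays, 1 point per array, with the detection limit dashed. GCNT2 stands at 9104 in HMLE Gcnt2, FOXQ1 is lowest among the 3 HMLE arrays at 299 in the array labelled Foxq1, and IRX5 is near the limit in all 3 SUM159 arrays.

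The first comparison concerns genes downstream of Foxq1, as the array labelled Foxq1 against HMLE LacZ. Genes of the mesenchymal list were higher in the array labelled Foxq1 and genes of the epithelial list were lower. Among the mesenchymal list, 20 of 29 detected members were at least 2-fold higher and none was at least 2-fold lower. Among the epithelial list, 20 of 29 detected members were at least 2-fold lower and none was as much higher. Across all 11165 genes compared, 736 were at least 2-fold higher and 664 lower, 12.5% of the genes against 3.83% in the reference pair. Beyond percentile 99 of the reference spread for their intensity the balance turned, with 149 higher and 261 lower. With cyclic loess run on top of the quantile-normalized values the 2-fold numbers were 592 higher and 763 lower. With the mean of probes they were 640 and 658.

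The proteoglycan genes DCN (decorin) and BGN (biglycan) were 17.1-fold and 14.1-fold higher in the array labelled Foxq1 than in LacZ, although a dimmer DCN probe differed by only 0.15 on the log2 scale. PDGFRB, the platelet-derived growth factor receptor beta of mesenchymal cells, was 9.95-fold higher, the collagen gene COL1A2 5.69-fold, and PCOLCE, an enhancer of procollagen cleavage, at least 5.73-fold. The intermediate filament gene VIM was 2.1-fold higher. CDH2 (N-cadherin) and FN1 (fibronectin) went the other way, 1.85-fold and 1.63-fold lower, and these and the VIM difference lay inside the reference spread for genes of like intensity. The other largest differences upward were in APOE, an apolipoprotein (11.8-fold), OLFML2A (11.3-fold), the steroid-metabolizing reductase AKR1C3 (9.50-fold), the cytochrome P450 gene CYP1B1 (9.19-fold), IGFBP4, which binds insulin-like growth factors (8.74-fold), and the G protein subunit GNG11 (7.47-fold). The mesenchymal median was 1.18, above every one of 10000 random lists matched on expression, whose middle range, from percentile 2.5 to 97.5, was -0.18 to 0.31.

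CDH1 (E-cadherin) was 6.95-fold lower in the array labelled Foxq1, the tight junction genes CGN (cingulin) and CLDN7 were 9.01-fold and 8.84-fold lower, and MAL2, a protein of apical transport, was 9.91-fold lower. EPCAM was only 1.49-fold lower. Basal and myoepithelial genes were lower as well, 7 of 18 by at least 2-fold, among them the skin-type protease KLK7 (15.1-fold, with another probe lower by 0.85 on the log2 scale), the desmosomal cadherin DSG3 (6.74-fold) and the keratin KRT15 (4.30-fold). Of the luminal list 5 of 16 members were lower, with KRT18 at least 5.42-fold and the forkhead gene FOXA1 at least 5.01-fold lower, while MLPH (melanophilin) was 3.59-fold higher. The list medians were -1.47 for the epithelial, -0.87 for the basal and -0.27 for the luminal genes, the first pair below all 10000 random lists and the luminal at percentile 1.26. The genes lowest against LacZ also included ANXA8, an annexin (27.8-fold), the calcium-binding protein S100P (at least 18.4-fold), PI3, the protease inhibitor elafin (14.3-fold), and GNG12 (at least 17.2-fold). Others with large differences were ALYREF of mRNA export (at least 19.1-fold), the amino acid transporter chain SLC3A2 (at least 19.3-fold), the proteasome subunit PSMC4 (17.6-fold) and the spectrin SPTBN1 (15.6-fold, with another probe lower by 0.62 on the log2 scale). These single-gene differences are open to the probe differences of that array given with the plot of probe pairs. The chaperonin gene TCP1 was inconsistent: its brightest probe was 19.8-fold lower and its other probe was higher by 0.65 on the log2 scale.

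Interferon response genes were higher in the array labelled Foxq1, 12 of 28 by at least 2-fold (median 0.81, above all random lists), with the antiviral genes OASL 5.20-fold (another probe 0.54 on the log2 scale) and IFI44L 3.92-fold higher. OAS2 was 4.42-fold higher by its brightest probe, but its probes differed in sign. Antigen presentation genes had a median of 0.62, with HLA-F 2.69-fold higher and 3 of 14 at least 2-fold higher. The hypoxia and glycolysis list had a median of 0.48 with PGM1 2.53-fold higher. ALDOA (aldolase) was inconsistent, 2.41-fold higher by its brightest probe and lower by 6.04 on the log2 scale by another. Matrix protease genes went both ways, 4 higher and 4 lower of 21 (median -0.31, percentile 0.360): the inhibitor TIMP2 was 3.61-fold higher, MMP9 11.3-fold lower and MMP10 at least 6.15-fold lower. Targets of EGFR and MAPK signalling had a median of -0.24 (percentile 2.17), with DUSP1 2.94-fold higher and the ligand TGFA 2.97-fold lower. Cell cycle genes had a median of 0.16, inside the random range, although FOXM1, a mitotic transcription factor, was 3.07-fold higher and the ribonucleotide reductase gene RRM2 10.2-fold lower. Medians inside the range of random lists were also found for stem cell associated genes (-0.33), inflammatory cytokines (0.13), the TGF-beta (0.04) and WNT (0.16) lists, integrins (0.19), the unfolded protein list (0.31), p53 targets (0.22), Iroquois and HOX genes (0.04) and ribosomal proteins (-0.07). Glycosyltransferases, cholesterol synthesis and leukocyte markers had medians of 0.04, 0.08 and -0.07, also inside the range, with means of the opposite sign. Within these lists ALDH1A3, an aldehyde dehydrogenase, was 6.68-fold lower, the activin inhibitor FST 6.80-fold lower, CTNNB1 (beta-catenin) 9.12-fold lower, GDF15 4.62-fold higher, ITGA10 5.82-fold higher and the prostaglandin synthase PTGS2 4.13-fold lower.

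Probes of the same gene differed in the array labelled Foxq1 more often than in any other comparison of 2 arrays of 1 line. Of 649 genes with 2 or more probes above an intensity of 500 in either array, 90 (13.9%) had probes whose differences from LacZ lay more than 4-fold apart. This held for 0 of 613 genes for Gcnt2 against LacZ and 0 of 646 in the reference pair. The differences were mostly downward. In all of the 90 genes but ZYX the lowest probe was at least 2-fold lower than in LacZ, and in most the highest probe lay within 2-fold of LacZ. Counts of lower genes in that array are open to this. Among the 649 genes, 46 were at least 2-fold lower by their brightest probe, 30 of them also by the median of their other probes, and 52 were higher, 29 of them also by the others. When each gene was represented by the detected probe nearest to 0, an alternative chosen after seeing the data, 635 genes were higher and 545 lower, and the lists counted 17 mesenchymal and 7 interferon genes higher and 20 epithelial and 6 basal genes lower. Of 4770 probes above an intensity of 500 in the other 7 arrays, 156 were lower in the array labelled Foxq1 than in each of them by at least 2-fold and 12 were higher; for Gcnt2 these numbers were 10 and 1. Most genes have 1 probe on this array, which leaves no second probe to compare.

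**Figure D2:**
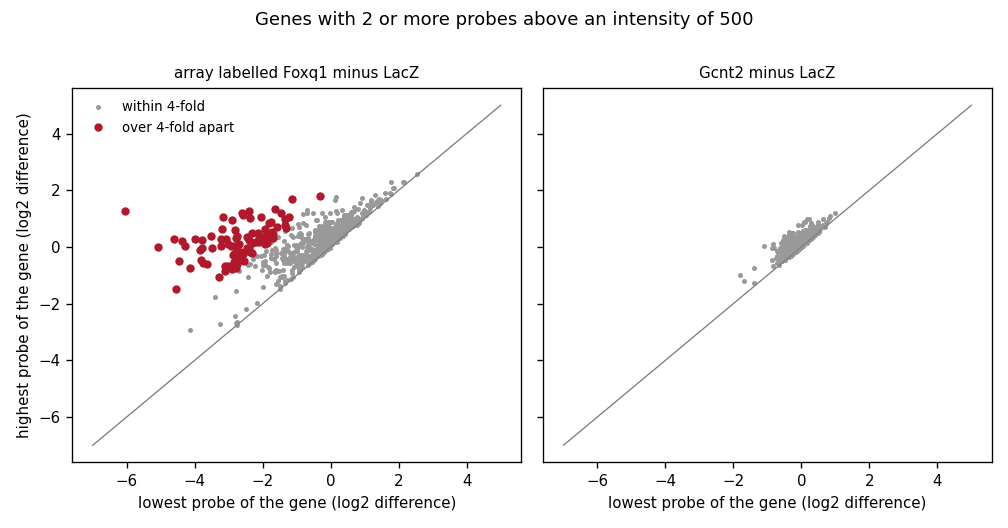
Lowest against highest log2 difference from HMLE LacZ among the probes of each gene with 2 or more probes above an intensity of 500, 1 point per gene, for the array labelled Foxq1 (left) and for Gcnt2 (right). On the diagonal all probes of a gene give the same difference; 90 genes lie more than 4-fold off it on the left and 0 on the right.

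HMLE Gcnt2 was compared with HMLE LacZ in the same way. Fewer genes differed: 30 were at least 2-fold higher and 90 lower among 10790, 1.11% against 3.83% in the reference pair. Only 1 higher and 16 lower genes exceeded percentile 99 of the reference spread for their intensity. These counts, and the genes named below, leave out the rise of GCNT2 itself. Its brightest probe over all arrays lay under the detection limit in both HMLE arrays compared here and is not the probe that was at least 81.0-fold higher. Mesenchymal genes were lower, 14 of 29 by at least 2-fold (median -0.94), and interferon response genes were lower, 8 of 27 (median -0.58). Epithelial and basal genes had medians of 0.54 and 0.50, with 1 member of each list at least 2-fold higher. All 4 medians lay outside every one of 10000 random lists.

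The collagen genes COL5A2 and COL1A1 were 4.55-fold and 3.73-fold lower in Gcnt2, the cadherin CDH11 4.15-fold, DCN 3.80-fold, CDH2 2.63-fold and VIM 2.40-fold lower. The largest differences downward were in the proteoglycan SRGN (serglycin, 5.44-fold) and the cationic amino acid transporter SLC7A2 (5.39-fold), followed by the interferon-induced gene IFI27 (4.59-fold), the heparan sulfate sulfotransferase HS3ST3A1 (4.24-fold), NREP (3.62-fold) and ANKRD1 (3.62-fold). Of the interferon list, IFI44L was at least 2.51-fold and OAS2 at least 2.61-fold lower. Upward, the epithelial cytokine IL36G was 2.93-fold higher, the galectin genes LGALS7B and LGALS7 2.51-fold and 2.29-fold, the protease FURIN 2.49-fold, the tricellular junction gene LSR 2.47-fold, the kinase PIM1 2.40-fold, WNT7B 2.31-fold, PHACTR3 2.29-fold and the nuclear receptor PPARD 2.25-fold. The folds of LSR and PPARD are of their brightest probes, and another probe of each was higher by only 0.08 and 0.006 on the log2 scale. GPM6B was 2.39-fold higher by its brightest probe, but its probes differed in sign. In the epithelial and basal lists, CLDN1 (claudin-1) was 2.03-fold and the laminin chain LAMB3 2.13-fold higher, and CDH1 1.65-fold higher. FN1 and EPCAM were 1.28-fold and 1.1-fold lower, and the probes of CD44 differed in sign.

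Other lists moved less between Gcnt2 and LacZ. Cell cycle genes had a median of -0.19 (percentile 0.05) with no member 2-fold apart. The TGF-beta list had a median of -0.24, with the ligand BMP2 2.18-fold higher and its inhibitor GREM1 at least 2.68-fold lower, but the median was -0.09 once values under the detection limit were raised to it. Medians of 0.19 for matrix proteases, 0.17 for EGFR and MAPK targets, 0.17 for integrins and 0.16 for glycosyltransferases lay at percentiles 99.8, 98.6, 97.5 and 98.2, each with at most 1 member 2-fold apart in either direction, and with dim values at the limit the glycosyltransferase median was 0.10, inside the range. The glycosyltransferase FUT3 was 2.02-fold higher, the EGFR ligand HBEGF 2.02-fold and the protease ADAM8 2.03-fold. In the WNT list WNT5A was 2.64-fold and the receptor FZD2 2.45-fold lower, with a median of -0.02 inside the range. The inflammatory list had a median of 0.13, inside the range, with TNFAIP3, a brake on NF-kB, 2.14-fold higher and IL6 2.10-fold lower. Also inside the range were the luminal (0.13), stem cell (0.10), Iroquois and HOX (0.03), hypoxia (0.04), cholesterol synthesis (0.03), unfolded protein (0.10), p53 (0.01), antigen presentation (0.08) and ribosomal protein (-0.05) medians, of which the Iroquois and HOX and cholesterol synthesis means had the opposite sign. Most of the single differences named for Gcnt2 lie inside the reference spread. The counts per list rest on the same single arrays, and the reference pair also had list medians outside the random range, given below.

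**Figure D3:**
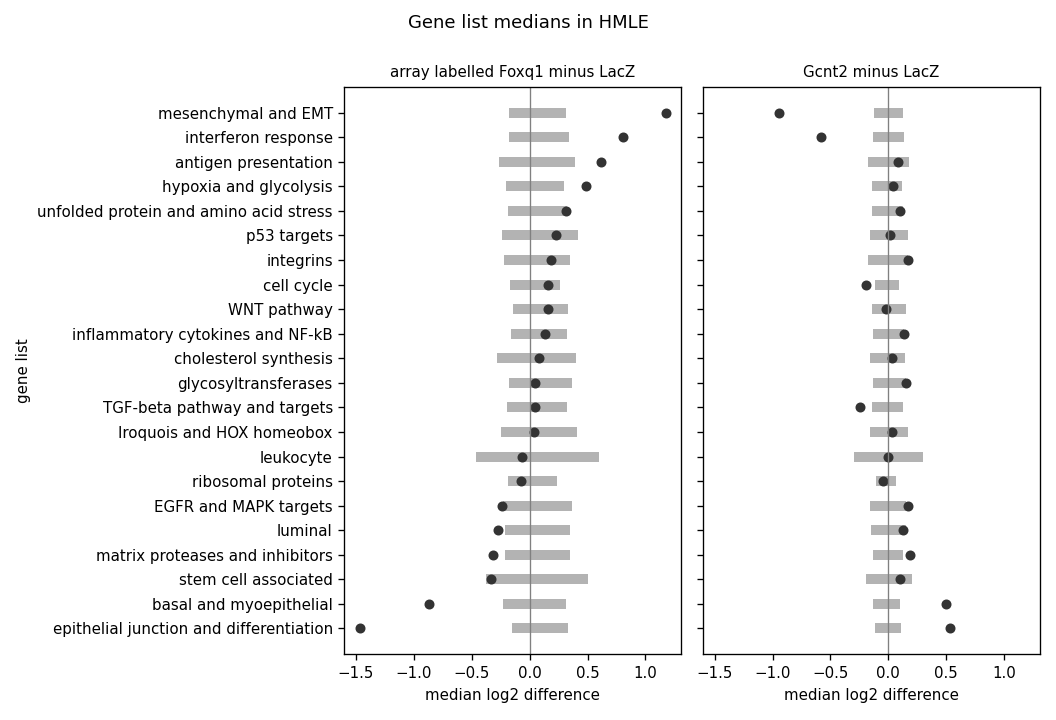
Median log2 difference from HMLE LacZ of each gene list with 5 or more detected members (points), for the array labelled Foxq1 (left) and for Gcnt2 (right), on a shared scale. Grey bars run from percentile 2.5 to 97.5 of 10000 random lists of like expression; the mesenchymal median is 1.18 on the left and -0.94 on the right, the epithelial -1.47 and 0.54.

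The differences of both HMLE arrays from LacZ were then set against each other, since both use the same control. Among genes at least 2-fold apart from LacZ in both arrays, those that differed in opposite directions outnumbered those that differed in the same direction. Of the 11383 genes detected in any of the 3 arrays, 41 were at least 2-fold higher in the array labelled Foxq1 and 2-fold lower in Gcnt2, among them VIM, DCN, WNT5A and IFI44L, where independent lists would share 5.82. Another 11 were lower in the array labelled Foxq1 and higher in Gcnt2, among them SOX9, HBEGF and FUT3, where independent lists would share 1.75. Only GPM6B was higher in both (1.94 for independent lists), and 9 genes were lower in both (5.25), among them ANKRD1 and the phosphatase DUSP4.

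Across these genes, which are not independent replicates, Pearson's r was -0.0574 and the Spearman rank correlation 0.0388. Unchanged arrays simulated against 1 shared control gave an r of 0.501, 70.3 genes higher in both and 69.4 lower in both with the SUM159 reference noise, and 13.2 and 12.3 with noise taken from the HMLE pair, a choice made after seeing the data. That r follows from equal noise in all simulated arrays, whatever its size. The real differences had unequal standard deviations, 0.708 for Foxq1 and 0.322 for Gcnt2, so 0.501 is no expectation for them. The HMLE noise is itself taken from the Gcnt2 difference. The covariance was -0.0127 against a simulated 0.110 with the reference noise, a difference of -0.123, and against 0.0511 with the HMLE noise. Differences had the same sign in 53.2% of genes against 66.6% simulated, a share that equal noise also fixes. A shared control adds differences in the same direction, so part of that overlap may come from it, and it adds none in opposite directions.

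**Figure D4:**
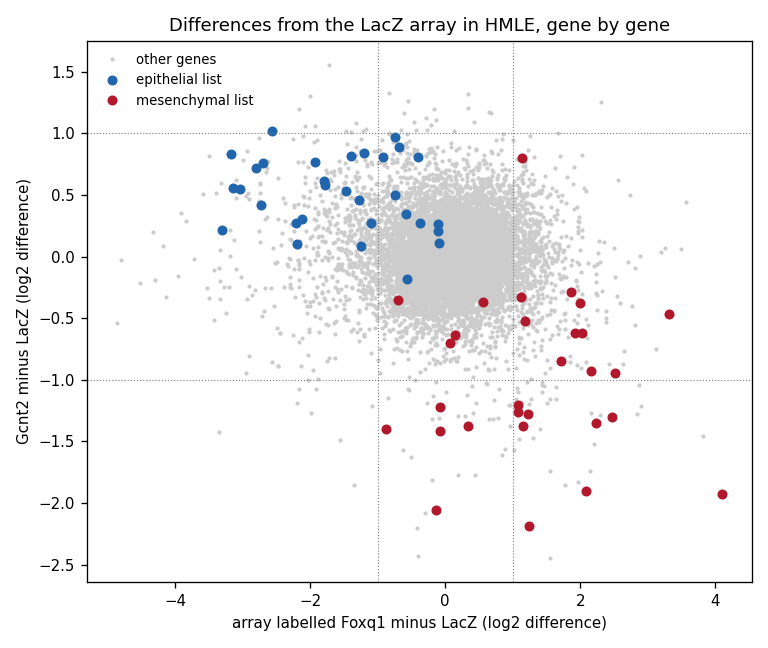
Log2 difference from HMLE LacZ in the array labelled Foxq1 (horizontal) against that in Gcnt2 (vertical), 1 point per gene detected in any of the 3 HMLE arrays, with the epithelial list in blue, the mesenchymal list in red and dotted lines at 2-fold. Most mesenchymal genes lie at lower right and most epithelial genes at upper left; across all 11383 genes Pearson's r is -0.0574.

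The next comparison concerns genes downstream of IRX5, as the array labelled IRX5 against SUM159 LacZ and, as a second control, against untransfected SUM159. Inflammatory cytokine genes and cell cycle genes were lower in the array labelled IRX5, and genes of the unfolded protein and amino acid stress response were higher. The controls also differed from each other in these lists, as given below for the reference pair. LacZ itself had lower cell cycle and higher unfolded protein medians than the untransfected array, so the differences from the untransfected array include that shift. Its inflammatory median was higher, which adds to the difference from LacZ. Cancer-testis antigens were lower mainly against LacZ. Against LacZ, 131 genes were at least 2-fold higher and 235 lower among 10798 (3.39%), close to the 3.83% of the reference pair. Percentile 99 of the reference spread was exceeded by 17 and 63, 0.74% of the genes, no more than the 1.01% in the reference pair itself. Against both controls, 82 genes were higher and 97 lower, where 3 arrays simulated with the reference spread alone gave 68.0 each way (46 to 88 higher and 53 to 94 lower in 100 simulations). That spread includes any difference the vector or culture made. With noise from the HMLE pair of Gcnt2 and LacZ, a choice made after seeing the data, the simulation gave 12.2 higher and 12.5 lower (4 to 23 and 6 to 20), so the number expected by chance is not settled. Each of the other SUM159 arrays also stood apart from the remaining pair, LacZ with 80 higher and 9 lower and the untransfected array with 89 and 127.

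The chemokine gene CXCL8 (interleukin 8) was 13.9-fold lower than in LacZ and 12.6-fold lower than in the untransfected array. CD24, a surface sialoglycoprotein used as a luminal marker, was at least 11.2-fold lower than in LacZ and at least 12.0-fold lower than in the untransfected array. KYNU, kynureninase of tryptophan breakdown, was 10.9-fold lower than in LacZ and 5.82-fold lower than in the untransfected array, and PTGES, a prostaglandin E synthase, 5.77-fold lower than in LacZ and 6.39-fold lower than in the untransfected array. Also lower, with the folds against LacZ and then the untransfected array, were GAGE4, a cancer-testis antigen (9.84-fold and 5.07-fold), the Notch ligand DNER (6.09-fold and 7.14-fold), the adhesion protein VCL (vinculin, 5.73-fold and 4.73-fold), CRISPLD2 (at least 5.63-fold and at least 11.5-fold) and the carboxypeptidase CPA4 (at least 3.98-fold and at least 19.5-fold). Higher than in both controls, with folds in the same order, were NIBAN1 (6.92-fold and 8.71-fold), IGFBP3, which binds insulin-like growth factors (at least 6.50-fold and 5.28-fold), S100P (4.42-fold and 13.8-fold) and the sialyltransferase genes ST6GAL1 (3.99-fold and 3.79-fold) and ST6GALNAC3 (5.17-fold and 3.40-fold). Against LacZ the kinase gene RPS6KA2 was 4.07-fold higher, the ubiquitin ligase component RBCK1 4.38-fold, CCPG1 3.59-fold, the potassium channel KCNMA1 3.47-fold and the zinc finger gene ZSCAN31 3.67-fold higher. Among the fixed marker genes, CDH2, VIM, FN1, EPCAM and CD44 differed by at most 1.33-fold from LacZ, and CDH1 was under the detection limit.

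Of the inflammatory list, 9 of 19 members were at least 2-fold lower than in LacZ and none higher (median -0.62), with IL6 10.8-fold and TNFAIP3 4.66-fold lower. IL6 was itself 4.76-fold higher in LacZ than in the untransfected array, against which IL6 and TNFAIP3 were 2.27-fold and 2.73-fold lower. Of the list, 5 were lower there and 3 higher (median -0.61), the latter including the chemokine CCL5 (3.17-fold). Cell cycle genes were lower than in LacZ with 5 of 30 at least 2-fold lower (median -0.61) and lower than in the untransfected array with 16 (median -1.06), among them thymidylate synthase TYMS (2.79-fold and 4.71-fold) and the replication helicase subunit MCM2 (2.14-fold and 2.19-fold). Cancer-testis antigens were lower than in LacZ, 8 of 15 (median -1.01, and -0.76 with dim values at the limit), with SPANXA1 3.92-fold lower than in LacZ and 5.14-fold lower than in the untransfected array. Against the untransfected array 5 of 14 were lower (median -0.28, just below the random range of -0.26 to 0.29). PAGE2 was 2.90-fold lower than in LacZ and differed by 0.05 on the log2 scale from the untransfected array. LacZ itself was higher than the untransfected array by 1.58 in PAGE2. Unfolded protein and amino acid stress genes were higher, 5 of 22 against LacZ (median 0.52) and 13 against the untransfected array (median 1.24). The chaperone HSPA5 was 3.60-fold higher than in LacZ and lower by 0.24 on the log2 scale than in the untransfected array, whereas TRIB3, induced by amino acid shortage, was 2.46-fold higher than in LacZ and 11-fold higher than in the untransfected array. Medians below all random lists against LacZ were also found for cholesterol synthesis (-0.66) and matrix proteases (-0.44), and the hypoxia list lay at -0.20. In these lists INSIG1 was 2.36-fold lower than in LacZ and 1.10-fold lower than in the untransfected array, MMP3 3.26-fold lower than in LacZ and 1.68-fold lower than in the untransfected array and the hormone gene ADM 3.90-fold lower than in LacZ and 2.91-fold lower than in the untransfected array. INSIG1 was itself 2.15-fold higher in LacZ than in the untransfected array.

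Interferon response genes went opposite ways against the controls, with a median of -0.36 against LacZ (5 of 24 lower) and 0.27 against the untransfected array (3 of 23 higher), the latter 0.09 with dim values at the limit. IFIT2 was 3.74-fold lower than in LacZ and at least 2.31-fold higher than in the untransfected array. NKD2, a WNT inhibitor, was 7.75-fold lower than in LacZ and differed by -0.02 on the log2 scale from the untransfected array. Leukocyte markers, of which 5 were detected, had a median of 0.45 against LacZ, and 0.18 with dim values at the limit. Among them LAPTM5 was 3.32-fold higher than in LacZ and 5.66-fold higher than in the untransfected array, and CD14 2.64-fold higher than in LacZ and 7.02-fold higher than in the untransfected array. Both exceeded the reference spread against the untransfected array, where 4 markers were detected and no median was given. Inside the random range against LacZ were the epithelial (-0.21), mesenchymal (-0.02), basal (0.06), luminal (-0.07), stem cell (-0.14), TGF-beta (-0.14), WNT (0.21), EGFR and MAPK (-0.13), integrin (0.16), glycosyltransferase (0.07), Iroquois and HOX (0.21), p53 (0.13), antigen presentation (0.16) and ribosomal protein (0.13) medians, of which the WNT mean had the opposite sign. Within them S100A4, a calcium-binding protein of motile cells, was 4.90-fold lower than in LacZ and 4.20-fold lower than in the untransfected array, the integrin chain ITGB4 3.35-fold higher than in LacZ and 5.95-fold higher than in the untransfected array, and ID3, a target of BMP signalling, 2.77-fold lower than in LacZ and 5.67-fold lower than in the untransfected array. Against the untransfected array the mesenchymal median was -0.48 (8 of 26 lower), the EGFR and MAPK median 0.40, the hypoxia median -0.53, the matrix protease median -0.70, the cholesterol synthesis median -0.35 and the TGF-beta median -0.25, the last -0.15 and inside the random range with dim values at the limit. Inside the random range against the untransfected array were the epithelial (-0.23), basal (-0.11), luminal (-0.05), stem cell (0.12), WNT (-0.19), integrin (-0.32), glycosyltransferase (-0.12), Iroquois and HOX (0.08), p53 (-0.01), antigen presentation (0.22) and ribosomal protein (0.19) medians, of which the basal, glycosyltransferase and p53 means had the opposite sign.

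The reference pair, SUM159 LacZ against untransfected SUM159, had 275 genes higher and 141 lower in LacZ. Interferon response genes were higher in LacZ, 7 of 24 (median 0.40), with IFIT2 at least 8.63-fold and OASL 4.73-fold higher. The unfolded protein list was split, 9 higher and 3 lower of 22 (median 0.87), with the stress transcription factors ATF3 and DDIT3 6.27-fold and 5.72-fold higher and the chaperone genes HSPA5 and HYOU1 4.25-fold and 2.46-fold lower. GDF15, a secreted stress cytokine, was at least 11.3-fold higher, the pluripotency-associated factor KLF4 7.81-fold, CCL5 7.83-fold, IL6 4.76-fold, NKD2 7.62-fold and FOXQ1 2.30-fold higher. CCN2, a target of TGF-beta and YAP signalling, was 7.91-fold lower, SMAD6 4.32-fold, the collagen cross-linking enzyme LOX 4.52-fold and COL1A1 4.43-fold lower. Medians outside the random range were -0.51 for the cell cycle, -0.43 for WNT, -0.44 for integrins, -0.20 for hypoxia, 0.34 for EGFR and MAPK targets, 0.27 for inflammatory genes, 0.29 for cholesterol synthesis and 0.42 for the 5 leukocyte markers. Inside the random range were the epithelial (0.13), mesenchymal (-0.18), basal (-0.09), luminal (-0.08), stem cell (0.13), TGF-beta (-0.18), matrix protease (-0.12), glycosyltransferase (-0.13), Iroquois and HOX (-0.07), p53 (-0.05), antigen presentation (0.20), cancer-testis (-0.22) and ribosomal protein (0.04) medians, of which the luminal, p53 and cancer-testis means had the opposite sign.

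The design text also compares the 3 basal-like lines. Each line had genes at least 2-fold higher than both others, 735 in SUM1315, 482 in MDA-MB231 and 385 in SUM159, and genes 2-fold lower than both, 542, 309 and 275. SUM1315 and MDA-MB231 lay 2-fold apart in 2659 genes (r = 0.910), SUM1315 and SUM159 in 2310 (0.912) and MDA-MB231 and SUM159 in 1760 (0.933), with r taken across genes, which are not independent replicates. Folds for a line are given against the nearer of the other lines, and list medians are against the mean of the other lines. Among other lists, SUM1315 had higher interferon genes, MDA-MB231 lower homeobox genes, and SUM159 higher cancer-testis antigens and mesenchymal genes. Some lists given below lay further out than the homeobox genes in MDA-MB231 and the mesenchymal genes in SUM159. The epithelial cadherin CDH1 was under the detection limit in MDA-MB231 and SUM159 and read 175 in SUM1315.

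In SUM1315, 17 of 26 interferon response genes were at least 2-fold above the mean of the other lines and 1 below (median 1.28), with the antiviral genes IFI6 6.10-fold, IFIT1 3.13-fold and HERC5 3.05-fold higher. The developmental homeobox gene DLX5 was at least 82.3-fold higher, the collagen genes COL1A2 at least 79.9-fold and COL5A2 4.84-fold, LOX 28.1-fold, the collagen receptor DDR2 at least 23.5-fold, the glycoprotein GPNMB at least 27.9-fold and THNSL2 at least 19.97-fold higher. IRX5 itself was 8.99-fold and IRX3 7.58-fold higher, and 7 of 16 Iroquois and HOX genes were 2-fold higher (median 0.50, and 0.28 with dim values at the limit, inside the random range). Cancer-testis antigens were mixed: CTAG2 was at least 58.6-fold, MAGEA9B at least 26.1-fold and MAGEA1 14.1-fold higher, yet 7 of 14 were lower (median -0.84). Lower than in both other lines were the matricellular gene THBS1 (at least 131-fold), CXCL8 (at least 55.9-fold), EFEMP1 (at least 48.7-fold), IGFBP4 (at least 42.0-fold), S100A16 (at least 40.8-fold), CCN2 (10.3-fold) and the simple keratins KRT7 (at least 11.9-fold) and KRT8 (at least 10.4-fold). Inflammatory genes had a median of -0.85 (8 of 22 lower), basal genes -0.90 (-0.38 with dim values at the limit), EGFR and MAPK targets -0.49, luminal genes -0.39 and the TGF-beta list -0.33 (-0.23 with dim values at the limit, inside the range). Mesenchymal genes split into 9 higher and 8 lower, with a median of -0.04 and a positive mean, and the probes of the receptor TGFBR2 differed in sign. Also inside the range were the epithelial (-0.23), stem cell (-0.20), cell cycle (-0.27), WNT (-0.10), integrin (-0.27), matrix protease (-0.22), glycosyltransferase (-0.27), hypoxia (-0.05), cholesterol synthesis (0.21), unfolded protein (0.10), p53 (-0.09), antigen presentation (0.32) and ribosomal protein (-0.21) medians. In this array 151 of 4782 probes above an intensity of 500 in all other arrays were lower than in each of them by at least 2-fold and 56 were higher, and 11 of 697 genes had probes more than 4-fold apart against SUM159.

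In MDA-MB231, inflammatory genes had a median of 1.06 (-0.54 among members detected in every array compared), with 11 of 22 at least 2-fold higher and 5 lower: the cytokines IL1B, IL6 and IL11 were 13.2-fold, 7.50-fold and at least 7.10-fold higher and the superoxide dismutase SOD2 5.53-fold lower. Matrix proteases were higher (8 of 21, median 0.55), with MMP9 at least 22.2-fold and MMP1 at least 12.2-fold, as were EGFR and MAPK targets (7 of 18, median 0.68), with HBEGF 10.2-fold and the phosphatase DUSP6 3.73-fold higher. Of Iroquois and HOX genes 10 of 16 were lower and none higher (median -1.41), with MSX1 at least 10.6-fold and HOXC6 7.09-fold lower. Mesenchymal genes were lower (13 of 28, median -0.87), with COL6A3 16.6-fold and COL5A2 at least 10.1-fold lower, although CDH11 was 8.22-fold higher. Cancer-testis antigens were lower (10 of 14, median -1.47), MAGEA6 by at least 13.5-fold. The BMP targets ID1, ID2 and ID3 were 5.43-fold, 10.5-fold and 15.5-fold lower. Other genes above both lines were the calcium-binding CALB2 (32.8-fold, with another probe higher by 0.10 on the log2 scale), SHISA2 (at least 27.1-fold), MPZL2 (26.7-fold), dysferlin DYSF (24.8-fold), the sulfate donor enzyme PAPSS2 (20.3-fold), the peroxidase GPX3 (at least 16.7-fold), ESAM of endothelial junctions (at least 11.7-fold) and the class II chaperone CD74 (11.5-fold). Below both were BEX1 (at least 46.4-fold), the aminopeptidase ANPEP (at least 22.0-fold), SNURF (at least 19.7-fold, with another probe lower by 0.31), NETO2 (at least 19.3-fold) and EPB41L3 (at least 18.5-fold). Stem cell associated (0.64), basal (0.63) and glycosyltransferase (0.46) medians lay above the random range and the interferon median (-0.31) below it. With dim values at the limit the basal median was 0.30, inside the range. Inside the random range were the epithelial (0.13), luminal (-0.18), cell cycle (0.12), TGF-beta (-0.01), WNT (-0.02), integrin (-0.15), hypoxia (-0.18), cholesterol synthesis (-0.03), unfolded protein (-0.10), p53 (-0.14), antigen presentation (0.06) and ribosomal protein (-0.04) medians, of which the luminal and hypoxia means had the opposite sign.

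In SUM159, cancer-testis antigens were higher, 9 of 14 by at least 2-fold (median 2.31), with XAGE2 at least 60.4-fold, PAGE5 at least 36.4-fold and PAGE2 at least 22.0-fold higher. Mesenchymal genes were higher, 10 of 28 (median 0.55), with CDH2 64.7-fold, SPARC (osteonectin) at least 23.2-fold and DCN 11.3-fold higher. The Iroquois gene IRX2 was at least 273-fold higher, the pentraxin NPTX2 at least 60.4-fold, podoplanin PDPN at least 46.0-fold, FEZ1 75.3-fold (another probe higher by 0.79 on the log2 scale), the keratin KRT7 10.9-fold and FOXQ1 6.53-fold higher. TGF-beta genes (8 of 22 higher, median 0.43) and integrins (median 0.38, ITGA5 2.48-fold higher) lay above the random range, as did Iroquois and HOX genes (0.24). Interferon response genes were lower, 15 of 26 (median -1.25), with HERC5 at least 16.3-fold, IFIT2 at least 10.4-fold and IFIT1 7.49-fold lower, although BST2 (tetherin) was 8.42-fold higher. Antigen presentation genes were lower, 7 of 17 (median -0.78). Also lower than in both other lines were EPDR1 (at least 37.8-fold), COXFA4L3 (at least 29.8-fold), the adhesion receptor ADGRG1 (at least 21.0-fold, with another probe lower by 0.06 on the log2 scale), the ribosomal protein paralog RPL39L (24.0-fold), the urokinase gene PLAU (23.1-fold) and SOX9 (at least 10.02-fold). The inflammatory median was -0.70, with a mean of the opposite sign (0.01) and 0.16 among members detected in every array compared: CXCL8 was 2.25-fold and CCL20 5.81-fold higher while 7 of 22 members were lower. Glycosyltransferases had a median of -0.37, below the random range. Inside the random range were the epithelial (-0.09), basal (0.22), luminal (0.22), stem cell (-0.07), cell cycle (0.04), WNT (0.18), EGFR and MAPK (-0.26), matrix protease (-0.10), hypoxia (0.17), cholesterol synthesis (-0.18), unfolded protein (0.07), p53 (0.26) and ribosomal protein (0.14) medians. With dim values at the limit the integrin, glycosyltransferase and Iroquois and HOX medians were 0.25, -0.31 and 0.12, inside the range; among members detected in every array compared the integrin median was -0.0043 and the Iroquois and HOX median -0.038.

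**Figure D5:**
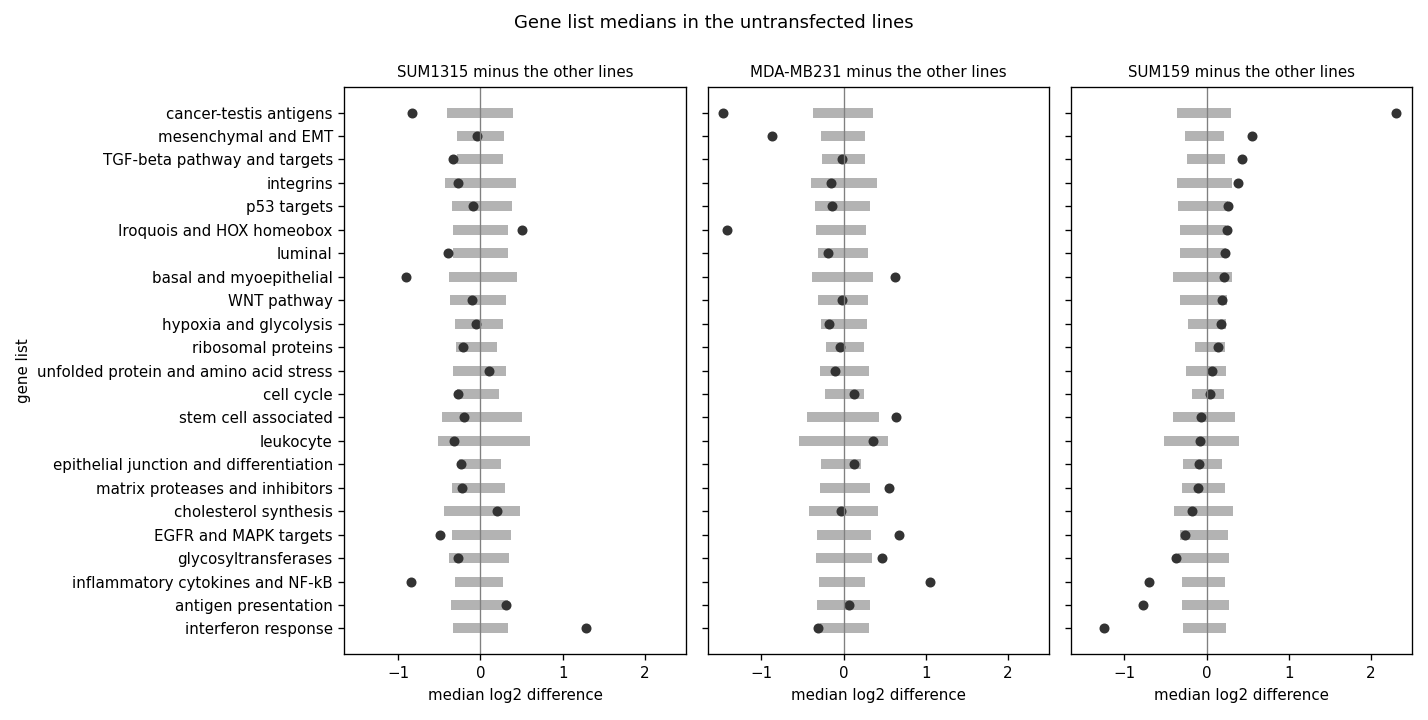
Median log2 difference of each gene list in each untransfected line against the mean of the other lines (points), on a shared scale, with grey bars from percentile 2.5 to 97.5 of 10000 random lists of like expression. Interferon genes are at 1.28 in SUM1315, -0.31 in MDA-MB231 and -1.25 in SUM159; cancer-testis antigens are at -0.84, -1.47 and 2.31.

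Of the markers of other cell types, only leukocyte markers reached 5 detected members. Besides the SUM159 medians already given, in the lines they had medians of -0.32, 0.36 and -0.08 for SUM1315, MDA-MB231 and SUM159, each inside the random range, and 0.00 for Gcnt2. The endothelial, adipocyte and melanocytic or neural lists had fewer than 5 detected members in every comparison and received no median, and the cancer-testis list had only 2 in both HMLE comparisons.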

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

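Mode subtraction, the limit of 200, dim values raised to the limit and the probe nearest to 0 were chosen after seeing the data; the other alternatives were planned, though the one at 0.05 was planned on detection p-values and run on the limit defined after the values were seen. Of the counts and the Foxq1 with Gcnt2 correlation (18 results), 183 values over 17 settings stayed within 1.5 times the value reported or close to it and 41 moved. These results were not scored for a turn in direction. The balance of higher and lower genes in the array labelled Foxq1 turned with the mean of probes (640 higher and 658 lower) and under cyclic loess. Of 91 list medians outside the random range, 837 values over 12 settings stayed close, 242 moved and 5 reversed. Of 250 differences of named genes, 1708 values over 8 settings stayed close, 291 moved and 1 reversed. The reversed value was ALDOA in the array labelled Foxq1, at -1.16 with the mean of its probes. The deposited values without background correction, cyclic loess, median scaling, the limit at 0.05, the limit of 200, the mean of probes, raised dim values and the probe nearest to 0 moved none of the counts over all genes by more than 1.5 times. Under cyclic loess, however, 43.7% of the genes 2-fold apart in the array labelled Foxq1 were higher, against 52.6% as reported. With an offset of 16, 59 genes were higher in Gcnt2. With detection required in every array compared, where fewer genes are counted, 428 genes were highest in SUM1315, 266 in MDA-MB231 and 175 in SUM159, and 160 lowest in SUM159; the inflammatory median was -0.54 in MDA-MB231 and 0.16 in SUM159 (0.0057 as a mean over the list reported), the SUM159 integrin median -0.0043 and its Iroquois and HOX median -0.038. With the mode subtracted, the array labelled IRX5 had 351 genes higher and 492 lower than LacZ and 178 and 207 against both controls, the array labelled Foxq1 1384 and 1044, and Gcnt2 160 and 237; LacZ and untransfected SUM159 lay apart in 999 genes and the LacZ arrays of both lines in 3013; 839 were lowest in SUM1315, 738 highest and 523 lowest in MDA-MB231, and 499 lowest in SUM159. That setting put the median of all genes at 0.12 for the array labelled Foxq1 (0.09 as reported, 0.10 at an offset of 16). At 1.5-fold, a lower threshold, the numbers were 687 and 807 for IRX5, 378 and 410 against both controls, 1977 and 1437 for Foxq1, 354 and 339 for Gcnt2, 1624 for the reference pair, 3998 for the LacZ arrays of both lines, and highest and lowest 1519 and 1163 in SUM1315, 1145 and 812 in MDA-MB231 and 810 and 702 in SUM159. With untransfected SUM159 in place of LacZ, IRX5 had 352 and 383; against the mean of the other HMLE arrays Gcnt2 had 338 and 283. The limma test of IRX5 against both controls, which assumes that its lone array varies like them with 1 residual degree of freedom, called 0 genes higher and 2 lower of 11165, CD24 (12.3-fold) and CXCL8 (13.2-fold), each at an adjusted p of 0.0354; at an unadjusted p under 0.05 there were 378 and 440. In 8 of 20 simulations with the reference spread and no gene changed the same test called 2 genes or more, so the calls carry little weight. Apart from fewer genes counted and the lower threshold, the cause was not tested. The planned setting without background correction is the same as the deposited values here, and the planned exchange of offsets was run as 16 in place of 50. With detection in every array compared, 6 list medians had too few members to be given, and 2 at the limit of 200. Leaving out an array was not possible with 1 array per group. No paired analysis was possible because the groups share only replicate number 1 and the results come from no test. Signal over background, a median of 1.45 times the mode, limits folds of dim genes to lower bounds, which hold on the background-corrected scale only.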

Other observations

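All tests of explanations in this part were chosen only after the results were seen. The control arrays of both transfected lines, SUM159 LacZ and HMLE LacZ, differ by line. Epithelial and basal genes of HMLE were much lower in SUM159: 17 of 18 basal genes and 25 of 29 epithelial genes were at least 2-fold lower, with medians of -4.88 and -3.14. The basal keratins KRT14 and KRT5 were at least 144-fold and at least 105-fold lower, FGFBP1, which releases fibroblast growth factors, at least 136-fold, the cadherins CDH1 and CDH3 at least 72.0-fold and at least 57.0-fold, and LAD1 of the basement membrane at least 74.4-fold lower. Matrix proteases were lower, 11 of 21 (median -1.03), with MMP9 at least 70.2-fold and the urokinase gene PLAU 49.2-fold lower, as were ALDH1A3 (83.4-fold), FST (61.2-fold), the chemokine CXCL1 (at least 25.7-fold) and CD24 (17.3-fold).

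Higher in SUM159 LacZ were cancer-testis antigens, 11 of 15 (median 2.63), with PAGE5 at least 84.4-fold and PAGE2 at least 65.9-fold higher, and unfolded protein and amino acid stress genes, 9 of 22 (median 0.79), with the stress factor DDIT3 7.75-fold and asparagine synthetase ASNS 7.65-fold higher. NKD2 was at least 33.5-fold higher, S100A4 17.1-fold, IRX2 16.5-fold and BST2 10.2-fold. Mesenchymal genes split, 8 higher and 9 lower of 30 (median -0.30, and -0.19 with dim values at the limit, inside the random range): the collagen gene COL6A3 was 7.07-fold higher and CDH11 at least 11-fold and TAGLN 8.55-fold lower. Integrin (-1.04), cholesterol synthesis (-0.89), luminal (-0.80), interferon (-0.46), cell cycle (-0.42), glycosyltransferase (-0.38), WNT (-0.37), TGF-beta (-0.35) and hypoxia (-0.30) medians lay below the random range. Inside it were the stem cell (0.41), EGFR and MAPK (0.04), Iroquois and HOX (0.25), p53 (-0.29), antigen presentation (0.15), ribosomal protein (0.23) and leukocyte (-0.22) medians, of which the stem cell, EGFR and MAPK and Iroquois and HOX means had the opposite sign. In all, 969 genes were higher and 1022 lower among 11215. The balance turned with the mode subtracted (1532 and 1481) and with detection required in both arrays (718 and 661). Between these arrays, 7 of 693 genes with 2 or more bright probes had probes more than 4-fold apart.

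The FOXQ1 probe was lower, not higher, in the array labelled Foxq1 (-2.59 against LacZ on the log2 scale). Had the labels of the HMLE LacZ and Foxq1 arrays been exchanged, FOXQ1 in Gcnt2 would lie near the array labelled Foxq1; it differed from that array by 2.33 and from the array labelled LacZ by -0.26, where percentile 99 of the reference spread for the intensities of these pairs is 1.95 and 1.51 (1.60 over all genes), which argues against an exchange. Loss of that single probe could give the same value: 76 of 3375 probes of like intensity (2.25%) were lower by as much in that array, against 0% in Gcnt2, and with 1 FOXQ1 probe this cannot be told apart from lower native FOXQ1 transcript beside a transgene the probe does not cover. Which applies, and what the construct holds, stays open, and no biological explanation was tested.

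In the array labelled Foxq1, probes of 1 gene often gave different answers (90 of 649 genes). The authors' normalization, which keeps the order of probes within an array, is argued against by 27 genes in which the brighter probe of HMLE LacZ was the dimmer one of the array labelled Foxq1, in 4 of all 649 genes by at least 2-fold in both arrays. The other pairs of 1 line, with at most 1 gene of differing probes, are no measure of the 27. For the 63 genes with the order kept, the part of the normalization is not settled. Probes of like intensity moved apart by at most 0.18 on the log2 scale in their median, where the smallest gap of these genes was 2.01. These medians come from values already quantile-normalized, a step that itself brings them near 0, so they cannot decide. Use of another transcript is not settled. Probes of 53 of 334 transcripts differed although annotated to the same transcript, with at most 1 in the other pairs. A further transcript that holds only some of these probes would give this too, and probe positions were not available. Loss of probes through RNA quality or hybridization stays open: probes lower than in every other array outnumbered higher ones 13 to 1 there (156 and 12), but also 10 to 1 in Gcnt2 (10 and 1), where no gene had probes that differed, and 2.70 to 1 in SUM1315, so this ratio does not decide. In most of the 90 genes 1 probe was lower and another lay within 2-fold of LacZ, which a loss of probes or another transcript would give. For single genes such as ALYREF, GNG12, SLC3A2 and RRM2, lower in that array, a loss of probes cannot be told apart from lower transcript.

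Mesenchymal genes were higher and epithelial genes lower in the array labelled Foxq1, and the opposite held in Gcnt2. Loss of probes is argued against for the mesenchymal part, since a loss gives lower values and 20 members were at least 2-fold higher. With the probe nearest to 0, 17 members stayed so, but members with 1 probe keep their value there and are not checked by it. For the epithelial part it is argued against since 20 of 29 members (69.0%) were lower, against 7.17% of genes of like intensity. The epithelial median of -1.47 also lay under the lowest of the random medians, -0.40. RNA of another line of the series is argued against, since 6 of the 20 higher mesenchymal members lay at least 2-fold above each of the 7 other arrays: PRRX1 (5.56-fold above the highest), COL1A1 (4.24-fold), COL3A1 (4.08-fold), DCN (3.59-fold), PDGFRB (2.71-fold) and THY1 (2.21-fold), of which those outside the rule for named genes were chosen after their values were seen. Another share of mesenchymal-like cells in the HMLE cultures cannot be told apart from a change within cells: 23 of 29 members were higher in the array labelled Foxq1 and lower in Gcnt2, as either would give, and 1 array per group keeps it open. An effect of the transgenes remains a hypothesis.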
